A study of Danio rerio with 9 samples.

How the data were processed

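The deposited table holds RNA-seq values for 9 libraries of adult zebrafish intestine, 3 from each of 3 groups. The samples, all of the AB laboratory strain, were taken on day 7. The labels give no treatment for mock fish and do not say whether these were injected or handled. Infected fish had received buffer and then 5 µL of Edwardsiella piscicida, a bacterial pathogen of fish, into the rectum. Trained infected fish had received 10 µL of yeast β-glucan at 10 mg/mL into the body cavity and had rested for 5 days before the bacteria were given. The labels speak of RNA isolated from individual samples and do not say whether a sample is the gut of 1 fish. The p-value of a single gene here therefore measures the spread between samples.

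RNA was extracted with Trizol and chloroform and made into libraries with an NEBNext Ultra II RNA kit. The authors deposited FPKM values (fragments scaled to gene length and library total), 1 column per library, without pooling replicates. The submitters' notes name HISAT2 2.1.0 as the aligner. The counting tool, the genome build, the annotation and any filter are not given in the sources used here, so no genomic coordinates are given. The table has 25432 Ensembl gene identifiers, of which 1483 are at 0 in every library. Gene names were taken from a table of Ensembl identifiers and symbols, which named 92.8% of the identifiers. The upper-case symbols in it are names carried over from human orthologs.

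The FPKM values of a gene stood in whole-number ratios across libraries, so fragments per gene could be recovered. For 22552 of the 23949 genes above 0 (94.2%), and for all 15321 genes tested, 1 gene length and whole fragment numbers gave the values within 0.01 fragments. The method was tested on simulated data of 4000 genes. Recovered totals ran from 13796745 to 16431067 fragments per library. The median length of the tested genes was 2365 nt, at which 1 fragment equals 0.0257 to 0.0306 FPKM and 3 fragments, the upper limit that a count of 0 allows, equal 0.0772 to 0.0919 FPKM. These limits cover counting error only.

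Genes with FPKM of at least 1 in at least 3 of the 9 libraries were kept, which left 15321. Values were taken as log2(FPKM + 1), and every log2 change below is a difference on that scale. All 9 libraries entered 1 limma fit (limma 3.58.1, statmod 1.5.0, R 4.3.3) with group as the only term. The fit used a mean-variance trend and robust moderation. The 3 comparisons were infected against mock, trained infected against infected, and trained infected against mock. Tests were two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested within each comparison, with a threshold of 0.05. With simulated log2 changes of 1 in 100 genes, the fit recovered 38, 35 and 47 of them in the 3 comparisons, and with changes of 2 it recovered 88, 88 and 92. The simulated noise was independent between genes, without variation that real libraries share, so these shares are not the power of this design.

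30 gene lists were written before the data were examined: immune cells and their mediators, gut epithelium, other organs that a dissected gut could carry, and metabolism and stress. 1137 of their 1267 names matched the table. Names without a match were left out, among them cd3e, cd3g and trac of the T cell list and saa of the antimicrobial and acute phase list. Each list was tested against the other genes with camera at a preset correlation of 0.01, adjusted over 90 tests, and again with camera at an estimated correlation. fry tested each list against no change, a different question from that of camera. Of 47 calls at the preset correlation, 1 held at the estimated correlation, and 3 tests of 2 lists (neutrophil and smooth muscle) passed with fry. The error of a list's median is a bootstrap standard error over its members from 2000 draws, so it measures spread over genes and not between samples. Camera at the preset correlation takes members as nearly independent, so its p-values do not measure the spread between samples either. Estimated correlations ran from 0.0035 (endocrine pancreas) to 0.76 (egg and gonad), with 0.70 for oxidative phosphorylation. A list's count is given over all genes tested and adjusted over the list alone.

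The rule for named genes was also fixed before the data were examined. It takes the 10 largest rises and falls among genes past the threshold with a proper symbol, a mean of at least 2 FPKM in the higher group and no overlap between groups, or the 5 of smallest p in a direction with none. It adds the up to 4 members of smallest p in each list described, the complement component 3 genes, and a fixed set of Th17, cytokine and acute phase genes. The organ markers prss1, fabp10a and ZAR1 fall outside this rule and were chosen after their values were seen. Some genes that the rule picks are not reported here.

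Other settings chosen beforehand were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, scaling without exocrine pancreas and hepatocyte genes, a replicate block, fits of only the 2 groups compared, an absolute log2 change of at least 1, and leaving out each library in turn. Added after seeing the data were voom on the recovered fragments, scores of hepatocyte, egg and gonad, or exocrine pancreas genes as covariates, and leaving out mock replicate 2 and trained infected replicate 1 together. A score is a library's mean log2(FPKM + 1) over the tested members of a list. The hepatocyte score used as a covariate left out members of the complement list, and the egg and gonad score those of the cell cycle list. Of the 66 hepatocyte genes 14 are on another list, so falls of lists that share them are partly built in. A list's median with its own score as a covariate is near 0 by construction. Relations between scores were tested by exact permutation of the 9 libraries (362880 orders, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3). Plots were drawn with Matplotlib 3.10.9. Tools that model raw counts were not run on the FPKM values.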

Results

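The 9 libraries of adult zebrafish intestine fell into 3 groups of 3: mock, infected with Edwardsiella piscicida, and trained infected, the last given yeast β-glucan before the same infection. β-Glucan is a cell wall sugar polymer used to induce trained immunity, a lasting change in innate immune cells after a first stimulus. By its title, the series asks whether training raises complement component 3 in the intestine and maintains Th17 cells, T cells that make interleukin 17 and interleukin 22. Libraries held 13796745 to 16431067 fragments in genes. 13711 to 15264 genes per library reached 1 FPKM.

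The libraries also carried transcripts of organs that lie against the gut, in shares that differed within groups. Exocrine pancreas genes, such as the trypsin gene prss1 (ENSDARG00000042993), made up 2.40% of summed FPKM in mock replicate 1 and 9.84 to 20.7% in the other 8 libraries. Hepatocyte genes made up 0.874% in trained infected replicate 1 and 0.174 to 0.455% elsewhere. Egg and gonad genes made up 0.832% in mock replicate 2, 0.324% in mock replicate 3 and 0.265% in trained infected replicate 1, against at most 0.111% in the other 6. The main axis of variation over the tested genes (first principal component, 49.5% of variance) did not follow the groups. It ran from 83.1 in mock replicate 2 to -66.5 in trained infected replicate 3. The egg and gonad score was likewise highest in the former (5.26) and lowest in the latter (0.211). Mock replicate 1 correlated more with infected replicate 1 (r = 0.942) than with mock replicate 2 (r = 0.873).

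**Figure D1:**
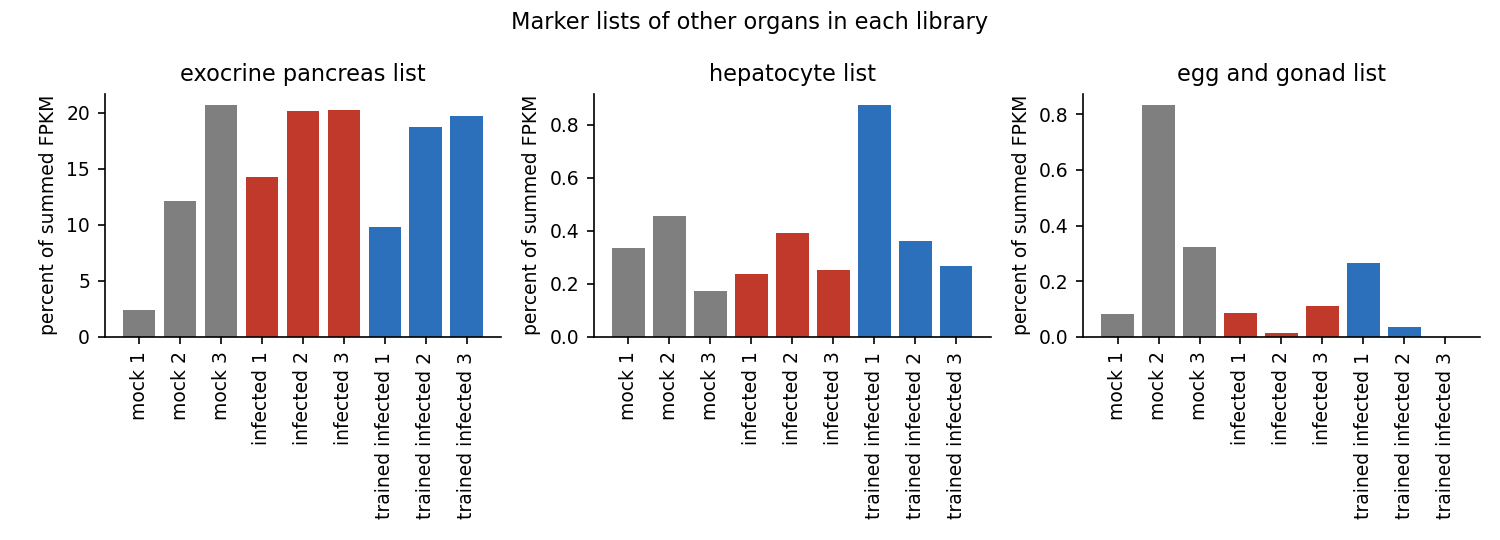
Bars give the percent of summed FPKM held by the exocrine pancreas, hepatocyte, and egg and gonad lists in each library, coloured by group. Mock replicate 1 has the lowest pancreas share (2.40%), trained infected replicate 1 the highest hepatocyte share (0.874%) and mock replicate 2 the highest egg and gonad share (0.832%).

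Infected intestine was compared with mock intestine to ask what the infection changed by day 7. Transcripts for serum amyloid A, hepcidin and interleukin 1 beta were among those that rose. SAA2 (ENSDARG00000045999), which encodes serum amyloid A, an acute phase protein, stood at 268 ± 178 FPKM (SD, n = 3) in infected and 5.92 ± 2.54 in mock intestine, a log2 change of 5.03 ± 0.56 (SE). STEAP4 (ENSDARG00000055901), a metal reductase induced in inflammation, rose from 2.92 ± 1.16 to 74.2 ± 5.36 FPKM, and hamp (ENSDARG00000102175), which encodes the iron hormone hepcidin, from 0.717 ± 0.449 to 16.36 ± 2.47 FPKM. il1b (ENSDARG00000098700), the inflammatory cytokine interleukin 1 beta, rose from 4.04 ± 1.56 to 35.09 ± 22.3 FPKM (limma adjusted p = 0.0449).

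In all, 46 of 15321 genes passed the threshold, and all 46 were higher in infected intestine (limma; 2021 genes had an unadjusted p under 0.05, 1037 of them lower). None of the 46 had overlapping groups, and across all genes tested 17.5% had groups without overlap, where chance gives 10%. The 10 largest named rises also held noxo1a (ENSDARG00000041294), an organizer of an epithelial NADPH oxidase, with a log2 change of 3.64, teni.1 (ENSDARG00000105096) with 3.35, and ACOD1 (ENSDARG00000069844), which makes the antimicrobial metabolite itaconate in macrophages, with 2.44. GPR84 (ENSDARG00000077308), a fatty acid receptor of myeloid cells, changed by 2.34, PLAC8 (ENSDARG00000043729) by 2.28 and PNP (ENSDARG00000078619), a purine salvage enzyme, by 2.16. No gene fell past the threshold (limma; smallest adjusted p of a named lower gene = 0.0668). The 5 named lower genes of smallest p were EIF4E2 (ENSDARG00000038585) (3.4 ± 0.180 against 7.89 ± 0.946 FPKM), pm20d1.1 (ENSDARG00000037551), GBA3 (ENSDARG00000031150), PPIL1 (ENSDARG00000015422) and uspl1 (ENSDARG00000034825).

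Neutrophil genes rose as a group, with a median log2 change of 0.77 ± 0.13 (bootstrap SE) over 24 tested members, 23 of them higher (camera adjusted p = 8.8e-15, and 0.0308 with an estimated correlation). Over all genes tested 2 members rose, and adjusted over the list alone 16 did. The 2 were MMP9 (ENSDARG00000042816), a matrix protease that neutrophils release (12.5 ± 1.94 against 3.44 ± 1.34 FPKM), and CSF3R (ENSDARG00000045959), the receptor of the growth factor that makes neutrophils (5.28 ± 0.878 against 0.982 ± 0.613 FPKM). This was the only one of the 16 lists called in this comparison that held with an estimated correlation.

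Other immune lists moved in both directions. The cytotoxic and natural killer cell list fell by a median of 0.41, with 11 of 11 lower (camera adjusted p = 0.0354, and 0.663 with an estimated correlation), a call that ended without mock replicate 1 (-0.18), mock replicate 3 (-0.40) or infected replicate 2 (-0.30). The T cell, antigen presentation and interferon response lists did not pass, at medians of -0.21, -0.20 and -0.15 (camera adjusted p = 0.180, 0.0523 and 0.698). The inflammatory cytokine and chemokine list had a median of 0.34 ± 0.14 (camera adjusted p = 1.2e-07, and 0.663 with an estimated correlation). Of its 46 tested members 3 rose over all genes tested, il1b, ACOD1 and tnfaip2b (ENSDARG00000058160), and 8 did adjusted over the list alone. PTGS2 (ENSDARG00000004539), the inducible prostaglandin synthase, had 5.56 ± 2.09 against 1.22 ± 0.799 FPKM (limma adjusted p = 0.0783). The macrophage list had a median of 0.29 ± 0.10 (camera adjusted p = 1.7e-05, and 0.506 with an estimated correlation). None of its 33 members passed over all genes tested (limma; 8 higher and 1 lower at an unadjusted p under 0.05), and 2 rose adjusted over the list alone. Its member of smallest p, MPEG1 (ENSDARG00000043093), the pore-forming protein of macrophages, had 24.7 ± 0.613 against 10.1 ± 2.69 FPKM (limma adjusted p = 0.0537). The antimicrobial and acute phase list had a median of 0.19 ± 0.32 and a mean of 0.65 (camera adjusted p = 7.4e-05, and 0.623 with an estimated correlation). 3 of its 30 members rose over all genes tested, STEAP4, hamp and MMP9, and 10 did adjusted over the list alone. SAA2 is not a tested member, since the listed name saa matched no symbol. The inflammatory median was 0.089 without mock replicate 2 and 0.15 without infected replicate 1, and the antimicrobial median was 0.29 without mock replicate 1, 0.88 without mock replicate 2, -0.041 without mock replicate 3, 0.63 without infected replicate 1 and 0.62 without infected replicate 3.

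**Figure D2:**
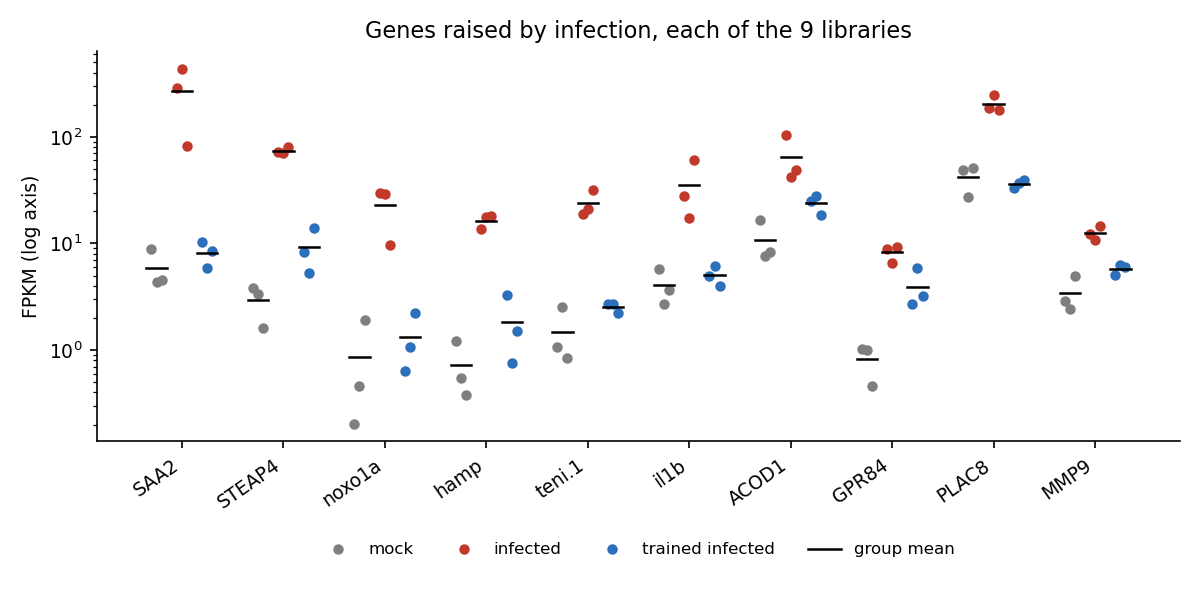
Points give FPKM (log axis) of 10 genes raised by infection in each of the 9 libraries, and black lines the group means. The 3 infected libraries lie above all 3 mock libraries for each gene, and trained infected libraries lie below the infected ones, for instance SAA2 with means of 5.92, 268 and 8.19 FPKM in mock, infected and trained infected intestine.

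Of the complement and Th17 genes that the series is about, only il1b passed the threshold after infection alone, and it no longer passed in 8 of the 9 limma fits with 1 library left out. The complement list had a median of 0.073 ± 0.11 with 22 of 40 members higher (camera adjusted p = 0.0179, and 0.723 with an estimated correlation). None of its members passed over all genes tested or adjusted over the list alone (limma; 4 higher and 0 lower at an unadjusted p under 0.05). c3a.1 (ENSDARG00000012694), the most abundant complement component 3 gene, had 48.2 ± 49.9 against 14.4 ± 13.8 FPKM (limma adjusted p = 0.483). The Th17 list had a median of 0.12 ± 0.07 (camera adjusted p = 0.0169, and 0.663 with an estimated correlation). Of its 30 members 1, il1b, rose over all genes tested, and adjusted over the list alone 5 rose and 1 fell. il6 (ENSDARG00000102318), an interleukin that favours Th17 cells, had 2.46 ± 1.06 against 0.262 ± 0.377 FPKM (limma adjusted p = 0.0995). The complement median was 0.042 without mock replicate 1, 0.32 without mock replicate 2, -0.048 without mock replicate 3 (call ended), 0.25 without infected replicate 1, -0.054 without infected replicate 2 (call ended) and 0.14 without infected replicate 3. The Th17 median was 0.29 without mock replicate 1, 0.0074 without mock replicate 2 (call ended), 0.068 without mock replicate 3, 0.20 without infected replicate 2 and 0.023 without infected replicate 3.

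Stromal and other organ lists moved as well. Endothelium and fibroblast genes rose by a median of 0.31 ± 0.083 (camera adjusted p = 2.4e-09, and 0.506 with an estimated correlation), with FLI1 (ENSDARG00000054632), an endothelial transcription factor, at 10.9 ± 1.27 against 5.85 ± 0.768 FPKM (limma adjusted p = 0.0882). Exocrine pancreas genes had a median of 1.22 ± 0.078 (camera adjusted p = 3.6e-08, and 0.663 with an estimated correlation), which was 0.33 without mock replicate 1. Cell cycle genes fell by a median of 0.76 ± 0.079, 49 of 50 lower (camera adjusted p = 8.5e-08, and 0.663 with an estimated correlation). None passed over all genes tested or adjusted over the list alone (limma; 6 lower at an unadjusted p under 0.05), with UBE2C (ENSDARG00000114670), a mitotic ubiquitin enzyme, at 24.6 ± 6.65 against 48.7 ± 12.6 FPKM (limma adjusted p = 0.264). Egg and gonad genes moved with them, with a median of -1.85 ± 0.22 and 27 of 27 lower (camera adjusted p = 4.5e-05, and 0.677 with an estimated correlation). Without mock replicate 2, the library richest in egg and gonad genes, the cell cycle median was -0.36, and without mock replicate 1 it was -1.17. The egg and gonad median was -1.23 without infected replicate 2.

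The count of 46 genes was 8 without mock replicate 2, 21 without mock replicate 3, 3, 4 and 12 without infected replicates 1, 2 and 3, and 18, 17 and 18 without trained infected replicates 1, 2 and 3. It was 16 with no filter, 6 when only the 2 groups compared were fitted, 30 with voom on recovered fragments and 18 with an egg and gonad score as a covariate, while STEAP4 and teni.1 passed in every setting run.

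Trained infected intestine was compared with infected intestine to ask what the earlier β-glucan changed, the main question of the series. No group received β-glucan without infection. Comparisons with trained infected fish therefore cannot separate an effect of β-glucan itself from an altered course of, or response to, infection. Several genes that infection had raised fell in trained fish. SAA2 fell from 268 ± 178 to 8.19 ± 2.19 FPKM (SD, n = 3), a log2 change of -4.59 ± 0.56 (SE, limma adjusted p = 0.0268). STEAP4 fell from 74.2 ± 5.36 to 9.17 ± 4.41 FPKM, hamp from 16.36 ± 2.47 to 1.84 ± 1.3, teni.1 from 23.8 ± 6.88 to 2.55 ± 0.286 and PLAC8 from 203 ± 37.4 to 36.4 ± 3.3. il1b had 5.01 ± 1.12 against 35.09 ± 22.3 FPKM and did not pass the threshold (limma adjusted p = 0.0545).

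In all, 22 genes passed the threshold, 13 higher and 9 lower in trained infected intestine (limma; 2596 genes had an unadjusted p under 0.05, 68.8% of them higher). Groups did not overlap for any of the 22, nor for 28.5% of all genes tested, where chance gives 10%. The falls also held ADAMTS1 (ENSDARG00000103519), a matrix protease, with a log2 change of -2.26, ggt1a (ENSDARG00000023526), which breaks down glutathione, with -1.95, the transcription factor ets2 (ENSDARG00000103980) with -1.24, and TXNRD3 (ENSDARG00000100374), a thioredoxin reductase, with -0.94. Among the rises were cald1b (ENSDARG00000086391), an actin-binding protein of smooth muscle (1.75), fgl2b (ENSDARG00000019686) (1.75), ACO1 (ENSDARG00000026376), a cytosolic aconitase that also regulates iron (1.73) and xirp1 (ENSDARG00000030722) (1.73). fam83ha (ENSDARG00000068849) (1.48), ANKRD11 (ENSDARG00000051886) (1.34), psip1a (ENSDARG00000104710) (1.26), mgaa (ENSDARG00000078784) (1.22) and the growth factor gene igf2b (ENSDARG00000033307) (1.19) rose as well.

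The 46 genes raised by infection were all lower in trained infected than in infected intestine. They had the opposite sign in this comparison (100%, 95% Clopper-Pearson interval 92.3 to 100%). The 2 comparisons share the infected libraries, and the 46 genes were selected for high values in them, so opposite signs are expected in part without any effect of training. 8 of the 46 fell past the threshold over all genes tested: SAA2, STEAP4, hamp, teni.1, PLAC8, ADAMTS1, ggt1a and ets2. The median return, the fall divided by the rise, was 0.60. In 100 simulations with equal infected and trained means, 992 genes on average passed in infected against mock, where the data gave 46, so they are no close match for genes selected in this way. Their median return was 0.135 (0.112 to 0.155), and 0.04 genes on average (0 to 1) also passed with the opposite sign in trained infected against infected. Among the 46 genes of smallest p in each simulation, 67.7% (54.3 to 80.4%) had the opposite sign. Over all 15321 genes, the correlation of the 2 log2 changes was -0.17, weaker than the -0.28 (-0.32 to -0.22) of the simulations, and their covariance was -0.037 against -0.057 (-0.069 to -0.044). For the 46 genes the values lay beyond the simulated ranges, while over all genes the opposition was weaker than simulated. The simulations drew genes independently and had far more genes passing. How much of the opposition exceeds what shared libraries give is therefore not settled. 4 of the 46 were still above mock past the threshold in trained fish, CSF3R and tnfaip2b among them. The interval takes genes as independent, and without mock replicate 1 the share was 90.5% of 63 genes.

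Inflammatory and stress lists fell. The inflammatory list fell by a median of 0.30 ± 0.075 (camera adjusted p = 0.000151, and 0.663 with an estimated correlation). None of its 46 members passed over all genes tested (limma; 12 lower and 4 higher at an unadjusted p under 0.05), and 4 fell adjusted over the list alone. il6 had 0.163 ± 0.149 against 2.46 ± 1.06 FPKM, PTGS2 1.16 ± 0.154 against 5.56 ± 2.09 FPKM and the cytokine gene il11a (ENSDARG00000037859) 0.972 ± 0.945 against 6.19 ± 1.26 FPKM (limma adjusted p = 0.0615 for each). The neutrophil list fell by a median of 0.34 ± 0.10 (camera adjusted p = 0.000472, and 0.435 with an estimated correlation), with MMP9 at 5.77 ± 0.680 against 12.5 ± 1.94 FPKM (limma adjusted p = 0.0838). The stress and immediate early list fell by 0.36 ± 0.059 (camera adjusted p = 7.2e-08, and 0.506 with an estimated correlation). JUNB (ENSDARG00000104773), an immediate early transcription factor, had 24.3 ± 0.780 against 59.7 ± 10.8 FPKM, while DDIT3 (ENSDARG00000059836), a factor of the unfolded protein response, had 24.4 ± 5.42 against 7.81 ± 3.05 FPKM (limma adjusted p = 0.0506 and 0.0568). The inflammatory median was -0.055 without infected replicate 1, and with a hepatocyte score as a covariate it was -0.11 and the call ended.

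Genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, had the smallest list p of this comparison. They fell by a median of 0.44 ± 0.021, with 66 of 69 lower (camera adjusted p = 1.6e-21, and 0.663 with an estimated correlation). None passed over all genes tested (limma; 39 lower and 0 higher at an unadjusted p under 0.05), and 1 fell adjusted over the list alone. cox8a (ENSDARG00000095273), a subunit of cytochrome c oxidase, had 64.5 ± 5.44 against 139 ± 28.6 FPKM (limma adjusted p = 0.0615), and COX7C (ENSDARG00000104537), another, had 59.06 ± 3.1 against 119.7 ± 16.1 FPKM. No library left out moved this median by over 1.5 times.

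Interferon, antigen presentation and T cell lists rose in trained infected intestine. The interferon response list rose by a median of 0.60 ± 0.13, 38 of 44 higher (camera adjusted p = 2.8e-05, and 0.663 with an estimated correlation), with parp14rs1 (ENSDARG00000040445) at 35.4 ± 5.63 against 10.3 ± 4.02 FPKM. Antigen presentation genes rose by 0.43 ± 0.10 (camera adjusted p = 0.00619, and 0.677 with an estimated correlation), with b2ml (ENSDARG00000015887), a beta 2 microglobulin, at 322 ± 29.8 against 125 ± 36.4 FPKM and cd40 (ENSDARG00000054968), a costimulatory receptor, at 22.0 ± 3.06 against 8.08 ± 3.00 FPKM. T cell genes rose by 0.36 ± 0.10 (camera adjusted p = 0.000976, and 0.663 with an estimated correlation), with RUNX3 (ENSDARG00000052826), a T cell transcription factor, at 9.93 ± 0.908 against 5.04 ± 1.23 FPKM and il7r (ENSDARG00000078970), the interleukin 7 receptor, at 18.2 ± 1.79 against 8.01 ± 2.71 FPKM. Only 32 of the 43 names on the T cell list matched a symbol, and cd3e, cd3g, trac and icos were among those left out. No member of the 3 lists passed over all genes tested (limma; 16, 7 and 8 higher and 0, 0 and 0 lower at an unadjusted p under 0.05), and 4, 3 and 1 rose adjusted over the list alone. Without infected replicate 2 the antigen presentation call ended (median 0.22), and the T cell median was 0.24 without trained infected replicate 2 and 0.58 without infected replicate 1. Cytotoxic and natural killer cell genes rose by 0.44 ± 0.08 (camera adjusted p = 0.0121, and 0.663 with an estimated correlation), a call that ended without infected replicate 2 (0.42) and at a mean FPKM of at least 5 (0.15). Smooth muscle genes rose by 0.25 ± 0.08 (camera adjusted p = 0.000728, and 0.623 with an estimated correlation), with 1 member, cald1b, over all genes tested and 7 adjusted over the list alone. The smooth muscle call ended at a mean FPKM of at least 5 (0.16), and the median was 0.16 without infected replicate 3 and 0.16 without trained infected replicate 1.

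**Figure D3:**
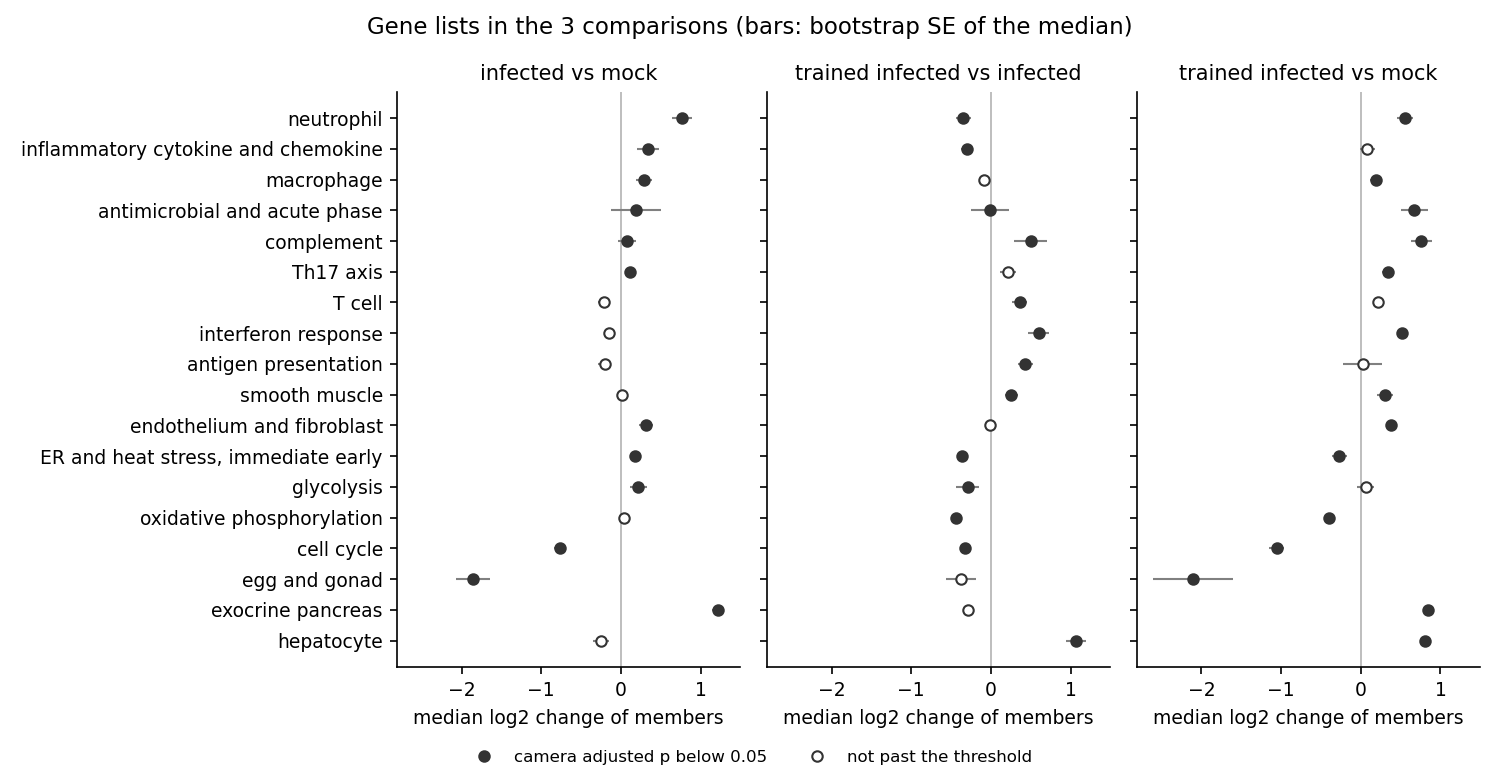
Points give the median log2 change of the members of 18 gene lists in the 3 comparisons, with the bootstrap SE of the median as bars, and filled points passed camera at the preset correlation. The neutrophil median is 0.77 after infection and -0.34 from infected to trained infected intestine, and oxidative phosphorylation is at -0.44 in the latter comparison.

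Complement genes, the subject of the series, rose as a list in trained infected intestine, by a median of 0.50 ± 0.20 with 33 of 40 members higher (camera adjusted p = 0.0207, and 0.727 with an estimated correlation). None passed over all genes tested or adjusted over the list alone (limma; 4 higher and 0 lower at an unadjusted p under 0.05). The libraries of the 2 groups overlapped. Summed FPKM of the list was 1684, 771 and 867 in trained infected replicates 1, 2 and 3, and 998, 1271 and 819 in the infected ones. Their complement scores were 3.85, 2.99 and 2.62 against 2.47, 2.95 and 2.46. c3a.1 had 77.8 ± 85.9 against 48.2 ± 49.9 FPKM, with 177 FPKM in trained infected replicate 1, and passed no test (log2 change 0.59 ± 1.008, limma adjusted p = 0.856). Of the other 7 complement component 3 genes, c3a.2 (ENSDARG00000087359), c3a.3 (ENSDARG00000052207), c3a.4 (ENSDARG00000093198), c3a.5 (ENSDARG00000053462), c3a.6 (ENSDARG00000043719), c3b.1 (ENSDARG00000093068) and c3b.2 (ENSDARG00000001818), none passed (limma; smallest adjusted p = 0.333 for c3b.1, 5.15 ± 4.34 against 1.3 ± 1.007 FPKM). c4b (ENSDARG00000038424), a component of the classical pathway, had 27.4 ± 9.47 against 13.4 ± 2.24 FPKM and cfh (ENSDARG00000100442), the inhibitory factor H, 11.2 ± 6.31 against 3.59 ± 0.799 FPKM (limma adjusted p = 0.150 and 0.192).

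Hepatocyte genes moved with complement. Their median was 1.07 ± 0.12 in this comparison (camera adjusted p = 1.7e-05, and 0.723 with an estimated correlation) and 0.56 without trained infected replicate 1. Without that library the complement median was 0.27 and its call ended, as it did without infected replicate 1 (0.44) or 3 (0.33), and it was 0.78 without infected replicate 2 and 0.98 without trained infected replicate 3. With a hepatocyte score as a covariate the complement median was 0.072. Across the 9 libraries the complement score followed the hepatocyte score, with Pearson r = 0.93 and Spearman rho = 0.88 (exact permutation p = 0.00066 and 0.0031, adjusted 0.0013 and 0.0037 over 6 tests of 3 relations). Without the 2 libraries farthest from the median hepatocyte score, r was 0.85, and it was 0.98 for deviations from group means. c3a.1 followed the hepatocyte score with r = 0.82 and rho = 0.88 (exact permutation p = 0.0070 and 0.0031, adjusted 0.0070 and 0.0037), 0.72 without the same 2 libraries and 0.98 within groups.

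**Figure D4:**
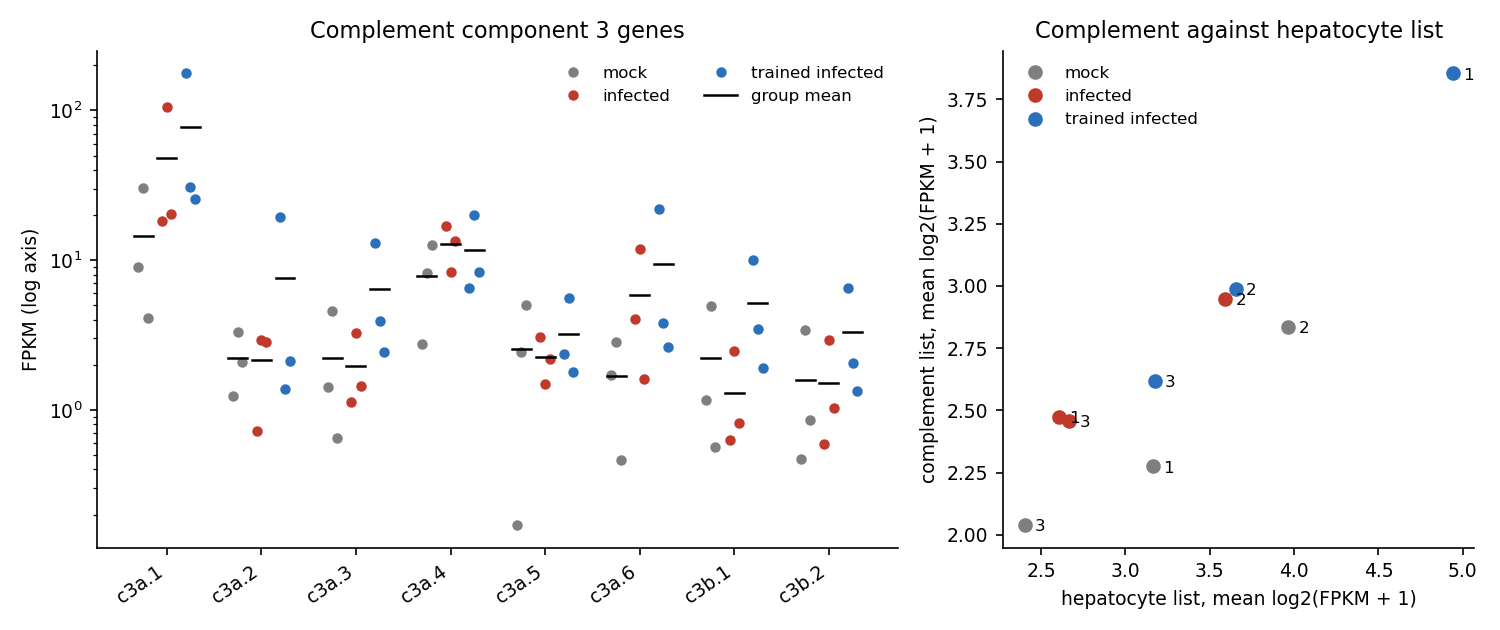
Left, points give FPKM (log axis) of the 8 complement component 3 genes in each library, with group means as black lines. Right, each point is a library's mean log2(FPKM + 1) over the complement list against that over the hepatocyte list, numbered by replicate, and trained infected replicate 1 is highest on both axes (r = 0.93).

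Th17 genes did not pass as a list, with a median of 0.22 ± 0.11 and 20 of 30 members higher (camera adjusted p = 0.342). None passed over all genes tested (limma; 5 higher and 2 lower at an unadjusted p under 0.05), and adjusted over the list alone 4 rose and 2 fell. rorcb (ENSDARG00000017780), a gene for the transcription factor of Th17 cells, had 3.17 ± 0.745 against 1.43 ± 0.276 FPKM (limma adjusted p = 0.108), and rorca (ENSDARG00000057231), its paralog, had 38.3 ± 9.15 against 27.5 ± 3.81 FPKM (limma adjusted p = 0.316). The cytokine gene il26 (ENSDARG00000045672) had 1.68 ± 0.414 against 0.446 ± 0.136 FPKM, il22 (ENSDARG00000045673) 4.83 ± 1.67 against 7.48 ± 4.93 FPKM and il22ra2 (ENSDARG00000039439), a decoy receptor of interleukin 22, 5.08 ± 0.243 against 2.11 ± 0.393 FPKM (limma adjusted p = 0.0643, 0.688 and 0.0571). cd4-1 (ENSDARG00000070668), the helper T cell coreceptor, had 3.09 ± 1.92 against 1.96 ± 0.715 FPKM and tnfa (ENSDARG00000009511) 1.51 ± 0.688 against 1.11 ± 0.483 FPKM. The interleukin 17 genes lay below the filter and were not tested. il17a/f3 (ENSDARG00000041976) had 20, 10, 9 fragments in the mock libraries, 3, 6, 10 in the infected and 12, 12, 17 in the trained infected ones. il17a/f2 (ENSDARG00000043934) had 2, 13, 7 fragments, then 2, 0, 0, then 0, 1, 0. il17a/f1 (ENSDARG00000043933) was listed at 0 in the 6 mock and infected libraries and had a mean of 0.0771 ± 0.134 FPKM in trained infected ones. The SD is larger than the mean, as when 1 library alone is above 0, so this trace value shows no rise across the group. The gene was above 0 in too few libraries for its fragments to be recovered. With a hepatocyte score as a covariate the Th17 list passed, at a median of 0.27.

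The count of 22 genes was 0 without infected replicate 1, infected replicate 2 or trained infected replicate 2 (1811, 1762 and 1917 genes at an unadjusted limma p under 0.05), 1 without trained infected replicate 1 or 3, 4 without mock replicate 3, 56 without infected replicate 3 and 534 without mock replicate 1. It was 440 when only the 2 groups compared were fitted, 55 with voom, 4 at a mean FPKM of at least 5, and 0 with a hepatocyte score as a covariate (2395 genes at an unadjusted limma p under 0.05). Mock libraries do not enter the log2 changes of this comparison. Leaving out a mock library, or fitting only the 2 groups, therefore changed the count through the shared estimate of the spread alone.

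Trained infected intestine was compared with mock intestine to see how far it lay from fish without infection. lrrc66 (ENSDARG00000093370) rose from 2.22 ± 1.42 to 16.2 ± 1.3 FPKM (SD, n = 3; log2 change 2.52 ± 0.45, limma adjusted p = 0.0456), and ACO1 from 2.32 ± 0.387 to 12.4 ± 1.11. DDIT3 rose from 5.67 ± 1.23 to 24.4 ± 5.42 FPKM. NDUFAF4 (ENSDARG00000077859), an assembly factor of respiratory complex I, fell from 17.1 ± 6.23 to 4.83 ± 1.31 FPKM and MVK (ENSDARG00000004130), the mevalonate kinase of sterol synthesis, from 7.77 ± 2.15 to 2.27 ± 0.798. Of the genes raised by infection alone, SAA2 stood at 8.19 ± 2.19 FPKM against 5.92 ± 2.54 in mock, il1b at 5.01 ± 1.12 against 4.04 ± 1.56 (limma adjusted p = 0.671) and STEAP4 at 9.17 ± 4.41 against 2.92 ± 1.16 (limma adjusted p = 0.0696).

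In all, 131 genes passed the threshold, 122 higher and 9 lower (limma; 3905 genes had an unadjusted p under 0.05, 2163 of them higher and 1742 lower). With median-of-ratios scaling 270 were higher and 226 lower. Groups did not overlap for any of the 131, nor for 26.6% of all genes tested, where chance gives 10%. Other named rises were RBP7 (ENSDARG00000070486), a retinol-binding protein (1.89 on the log2 scale), PDE5A (ENSDARG00000051915), a phosphodiesterase of smooth muscle (1.81), PDK2 (ENSDARG00000020876), which restrains entry of pyruvate into mitochondria (1.71), hhla2b.2 (ENSDARG00000086254) (1.63), ENSA (ENSDARG00000061644) (1.58) and lama3 (ENSDARG00000071462), a laminin of epithelial basement membranes (1.57). Other falls were cox17 (ENSDARG00000069920), a copper chaperone of cytochrome c oxidase (-1.49), POLR2L (ENSDARG00000058349), an RNA polymerase subunit (-1.3), POGLUT2 (ENSDARG00000031971) (-1.12), GBA3 (-1.07), bxdc2 (ENSDARG00000098935) (-0.97), ldlrb (ENSDARG00000026759), an LDL receptor (-0.88), and MRPL27 (ENSDARG00000032985), a mitochondrial ribosomal protein (-0.87).

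Neutrophil and macrophage lists passed camera at the preset correlation in trained infected against mock intestine. The neutrophil list was 0.56 ± 0.10 above mock (camera adjusted p = 0.000202, and 0.435 with an estimated correlation), with 1 member, CSF3R, over all genes tested (4.40 ± 0.763 against 0.982 ± 0.613 FPKM) and 9 adjusted over the list alone. The macrophage list had a median of 0.19 ± 0.07 (camera adjusted p = 0.0247, and 0.663 with an estimated correlation), with 2 members over all genes tested and 3 adjusted over the list alone. The 2 were mrc1b (ENSDARG00000038822), a mannose receptor (3.6 ± 0.639 against 0.761 ± 0.114 FPKM), and SPI1 (ENSDARG00000000767), the master transcription factor of myeloid cells (15.7 ± 1.47 against 6.04 ± 2.58 FPKM). The macrophage call ended without mock replicate 2 (0.14) or trained infected replicate 2 (0.16), and its median was 0.31 without mock replicate 1. Endothelium and fibroblast genes rose by 0.37 ± 0.05 (camera adjusted p = 7.4e-05, and 0.663 with an estimated correlation), with CXCL12 (ENSDARG00000037116), a stromal chemokine, at 32.2 ± 6.52 against 12.8 ± 2.75 FPKM. Smooth muscle genes rose by 0.31 ± 0.10 (camera adjusted p = 8.2e-05, and 0.550 with an estimated correlation), with 3 members over all genes tested and 5 adjusted over the list alone, MYH11 (ENSDARG00000009782), the smooth muscle myosin, among them at 47.5 ± 4.46 against 25.2 ± 1.58 FPKM. Interferon response genes rose by 0.51 ± 0.057 (camera adjusted p = 8.2e-05, and 0.663 with an estimated correlation), with eif2ak2 (ENSDARG00000068729), the antiviral kinase PKR, at 6.02 ± 0.709 against 2.82 ± 0.170 FPKM. The interferon median was 0.95 without mock replicate 1 and 0.21 without mock replicate 2.

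Complement genes were 0.76 ± 0.13 above mock, 35 of 40 higher (camera adjusted p = 0.000151, and 0.663 with an estimated correlation), with none past the threshold over all genes tested (limma; 10 higher and 0 lower at an unadjusted p under 0.05) and 5 adjusted over the list alone. c7a (ENSDARG00000042172), a component of the membrane attack complex, had 5.35 ± 0.570 against 2.11 ± 0.998 FPKM and cfp (ENSDARG00000094451), properdin, 11.3 ± 0.629 against 4.87 ± 1.36 FPKM (limma adjusted p = 0.0590 and 0.0598). c3a.1 had 77.8 ± 85.9 against 14.4 ± 13.8 FPKM (limma adjusted p = 0.217), and no other complement component 3 gene passed. Hepatocyte genes moved with them, at 0.81 ± 0.074 (camera adjusted p = 0.000212, and 0.761 with an estimated correlation). Without trained infected replicate 1 the complement median was 0.35, and the hepatocyte median was 1.22 without mock replicate 2, 0.48 without mock replicate 3, 0.23 without trained infected replicate 1 (call ended) and 1.26 without trained infected replicate 3. With a hepatocyte score as a covariate the complement median was 0.19 and the list still passed camera (adjusted p = 0.00793). The Th17 list rose by 0.34 ± 0.076 (camera adjusted p = 0.00351, and 0.663 with an estimated correlation), with none over all genes tested (limma; 9 higher and 0 lower at an unadjusted p under 0.05) and 4 adjusted over the list alone, il6r (ENSDARG00000104474) among its members of smallest p (6.12 ± 1.03 against 2.73 ± 0.591 FPKM).

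Cell cycle genes fell by a median of 1.05 ± 0.093 against mock, 48 of 50 lower (camera adjusted p = 2.1e-11, and 0.663 with an estimated correlation), with none over all genes tested (limma; 24 lower and 0 higher at an unadjusted p under 0.05) and 11 adjusted over the list alone. CDK1 (ENSDARG00000087554), the mitotic kinase, had 13.2 ± 4.64 against 27.2 ± 6.49 FPKM (limma adjusted p = 0.0867). Egg and gonad genes moved with them, at a median of -2.11 ± 0.50 (camera adjusted p = 3.9e-05, and 0.677 with an estimated correlation), which was -1.32 without trained infected replicate 3. Oxidative phosphorylation genes fell by 0.40 ± 0.034, 66 of 69 lower (camera adjusted p = 4e-11, and 0.663 with an estimated correlation), and by 0.24 without mock replicate 1. Exocrine pancreas genes had a median of 0.85 ± 0.051 (camera adjusted p = 0.00190, and 0.761 with an estimated correlation), which was 0.026 without mock replicate 1 (call ended) and 1.43 without mock replicate 3.

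The count of 131 genes was 0 without mock replicate 2 or 3, infected replicate 1 or any of the 3 trained infected replicates (limma; 2364 to 4192 genes at an unadjusted p under 0.05), 12 and 45 without infected replicates 2 and 3, and 2430 without mock replicate 1. It was 7 with a pseudocount of 0.1, 3 at a mean FPKM of at least 5, 496 with median-of-ratios scaling, 196 with voom, and 0 in a limma fit of only the 2 groups (3001 genes at an unadjusted p under 0.05).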

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

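The count for infected against mock was 46 (46 higher and 0 lower), and it was 29 with a pseudocount of 0.1, 16 with no filter, 7 with a replicate block, 6 with only the 2 groups compared, 30 with voom, 29 with the hepatocyte covariate, 18 with the egg and gonad covariate, 24 with the exocrine pancreas covariate and 6 without mock replicate 2 and trained infected replicate 1. With 1 library left out it ran from 3 (without infected replicate 1) to 63 (without mock replicate 1).

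The count for trained infected against infected was 22 (13 higher and 9 lower), and it was 11 with a pseudocount of 0.1, 4 at a mean FPKM of at least 5, 40 with quantile normalization, 150 with scaling without pancreas and hepatocyte genes (113 higher and 37 lower), 440 with only the 2 groups compared, 55 with voom, 63 with the egg and gonad covariate, 286 with the exocrine pancreas covariate and 3 without mock replicate 2 and trained infected replicate 1. It was 0 in limma fits with a replicate block (2581) and with the hepatocyte covariate (2395), with the number of genes at an unadjusted p under 0.05 in parentheses. With 1 library left out it ran from 0 (without infected replicate 1) to 534 (without mock replicate 1).

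The count for trained infected against mock was 131 (122 higher and 9 lower), and it was 7 with a pseudocount of 0.1, 7 with no filter, 3 at a mean FPKM of at least 5, 496 with median-of-ratios scaling (270 higher and 226 lower), 442 with quantile normalization (309 higher and 133 lower), 278 with scaling without pancreas and hepatocyte genes and 1 with the egg and gonad covariate. It was 0 in limma fits with a replicate block (3511), with only the 2 groups compared (3001), with the hepatocyte covariate (4480) and without mock replicate 2 and trained infected replicate 1 (3087), with the number of genes at an unadjusted p under 0.05 in parentheses. With 1 library left out it ran from 0 (without mock replicate 2) to 2430 (without mock replicate 1).

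The complement call for trained infected against infected, at a median of 0.50, was lost at 0.38 at a mean FPKM of at least 5, 0.072 with the hepatocyte covariate, 0.49 with the exocrine pancreas covariate and 0.27 without mock replicate 2 and trained infected replicate 1. It was also lost at the same median of 0.50 with an estimated correlation and with fry. With 1 library left out the median ran from 0.27 (without trained infected replicate 1) to 0.98 (without trained infected replicate 3). The complement call for infected against mock (0.073) was lost at 0.15 with quantile normalization and, at 0.073, with an estimated correlation and with fry, and with 1 library left out it ran from -0.054 (without infected replicate 2) to 0.32 (without mock replicate 2). It held at larger medians in other settings: 0.15 with a pseudocount of 0.1, 0.49 at a mean FPKM of at least 5, 0.12 with median-of-ratios scaling, 0.16 with voom, 0.24 with the hepatocyte covariate, 0.41 with the egg and gonad covariate, 0.20 with the exocrine pancreas covariate and 0.32 without mock replicate 2 and trained infected replicate 1.

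The Th17 call for infected against mock (0.12) was lost at 0.064 with no filter, 0.13 with the egg and gonad covariate and 0.0074 without mock replicate 2 and trained infected replicate 1 and, at 0.12, with an estimated correlation and with fry. With 1 library left out it ran from 0.0074 (without mock replicate 2) to 0.29 (without mock replicate 1). For trained infected against infected the Th17 list passed only at 0.27 with the hepatocyte covariate. The share of infection genes with the opposite sign, 100%, was 90.5% without mock replicate 1 and 98.3% with median-of-ratios scaling.

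Medians of these lists changed sign in infected against mock. Lysosome rich enterocyte list (0.073) was -1.1e-05 with no filter, -0.17 with the exocrine pancreas covariate and -0.035 without mock replicate 2 and trained infected replicate 1, and -0.10 (without infected replicate 3) to 0.16 (without mock replicate 3) with 1 library left out. Hepatocyte list (-0.24) was 0.15 with the egg and gonad covariate and 0.089 without mock replicate 2 and trained infected replicate 1, and -0.64 (without infected replicate 2) to 0.089 (without mock replicate 2) with 1 library left out. Cholesterol and fatty acid synthesis list (-0.42) was 0.066 with the exocrine pancreas covariate. Antimicrobial and acute phase list (0.19) was -0.041 (without mock replicate 3) to 0.88 (without mock replicate 2) with 1 library left out.

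Medians of these lists changed sign in trained infected against infected. Antimicrobial and acute phase list (-0.011) was 0.0062 with no filter, 0.038 at a mean FPKM of at least 5, 0.028 with quantile normalization and 0.012 with scaling without pancreas and hepatocyte genes, and -0.21 (without trained infected replicate 1) to 0.069 (without trained infected replicate 3) with 1 library left out. Cell cycle list (-0.33) was -0.68 (without trained infected replicate 1) to 0.045 (without trained infected replicate 3) with 1 library left out.

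Medians of these lists changed sign in trained infected against mock. Exocrine pancreas list (0.85) was -0.064 with the exocrine pancreas covariate. That score is made of the same genes, so the median is near 0 by construction and its sign carries no information.

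None of these named genes passed the threshold in infected against mock, and their log2 change turned sign. c3a.2 (-0.068) was 0.00303 with quantile normalization, 0.16 with the hepatocyte covariate, 0.75 with the egg and gonad covariate, 0.025 with the exocrine pancreas covariate and 0.17 without mock replicate 2 and trained infected replicate 1, and -0.30 (without mock replicate 1) to 0.32 (without infected replicate 1) with 1 library left out. c3a.3 (-0.0011) was 0.088 with a pseudocount of 0.1, 0.044 with median-of-ratios scaling, 0.093 with quantile normalization, 0.031 with scaling without pancreas and hepatocyte genes, 0.11 with voom, 0.25 with the hepatocyte covariate, 0.53 with the egg and gonad covariate, 0.25 with the exocrine pancreas covariate and 0.49 without mock replicate 2 and trained infected replicate 1, and -0.39 (without mock replicate 3) to 0.49 (without mock replicate 2) with 1 library left out. c3a.5 (0.14) was -0.64 with the exocrine pancreas covariate, and -0.52 (without mock replicate 1) to 0.67 (without mock replicate 3) with 1 library left out. c3b.1 (-0.33) was 0.20 with the egg and gonad covariate and 0.24 without mock replicate 2 and trained infected replicate 1, and -0.72 (without mock replicate 3) to 0.24 (without mock replicate 2) with 1 library left out. c3b.2 (0.023) was -0.057 with the exocrine pancreas covariate, and -0.35 (without infected replicate 2) to 0.50 (without mock replicate 2) with 1 library left out. il22 (0.12) was -0.19 without mock replicate 2 and trained infected replicate 1, and -0.33 (without infected replicate 3) to 0.40 (without infected replicate 2) with 1 library left out. rorcb (0.064) was -0.029 without mock replicate 2 and trained infected replicate 1, and -0.029 (without mock replicate 2) to 0.15 (without mock replicate 1) with 1 library left out. rorca (-0.14) was -0.25 (without mock replicate 2) to 0.016 (without mock replicate 3) with 1 library left out. tnfa (0.057) was -0.12 (without mock replicate 3) to 0.26 (without mock replicate 1) with 1 library left out.

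None of these named genes passed the threshold in trained infected against infected, and their log2 change turned sign. c3a.1 (0.59) was -1.15 with the hepatocyte covariate and -0.28 without mock replicate 2 and trained infected replicate 1, and -0.28 (without trained infected replicate 1) to 1.39 (without infected replicate 2) with 1 library left out. c3a.2 (0.85) was -0.17 with the hepatocyte covariate and -0.12 without mock replicate 2 and trained infected replicate 1, and -0.12 (without trained infected replicate 1) to 1.43 (without trained infected replicate 2) with 1 library left out. c3a.4 (-0.23) was 0.20 with the hepatocyte covariate and 0.066 without mock replicate 2 and trained infected replicate 1, and -0.68 (without trained infected replicate 2) to 0.066 (without trained infected replicate 1) with 1 library left out. c3a.6 (0.41) was -0.93 with the hepatocyte covariate and -0.41 without mock replicate 2 and trained infected replicate 1, and -0.41 (without trained infected replicate 1) to 1.02 (without infected replicate 2) with 1 library left out. c3b.2 (0.69) was -0.23 with the hepatocyte covariate. c3a.5 (0.31) was -0.058 (without trained infected replicate 2) to 0.56 (without trained infected replicate 3) with 1 library left out. il22 (-0.44) was -0.73 (without infected replicate 2) to 0.0068 (without infected replicate 3) with 1 library left out.

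None of these named genes passed the threshold in trained infected against mock, and their log2 change turned sign. c3a.2 (0.78) was -0.0043 with the hepatocyte covariate, and -0.19 (without trained infected replicate 1) to 1.36 (without trained infected replicate 2) with 1 library left out. c3a.5 (0.44) was -0.18 with the exocrine pancreas covariate, and -0.21 (without mock replicate 1) to 0.97 (without mock replicate 3) with 1 library left out. cd4-1 (-0.19) was 0.064 with the hepatocyte covariate and 0.18 without mock replicate 2 and trained infected replicate 1, and -0.52 (without trained infected replicate 2) to 0.22 (without trained infected replicate 1) with 1 library left out.

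Calls of these other lists ended in infected against mock without a change of sign. Cytotoxic and NK cell (-0.41) ended at -0.97 at a mean FPKM of at least 5 and -0.23 with the exocrine pancreas covariate. Lysosome rich enterocyte (0.073) ended at 0.11 with quantile normalization, 0.00353 with the hepatocyte covariate and 0.073 with the egg and gonad covariate.

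Calls of these other lists ended in trained infected against infected without a change of sign. Cytotoxic and NK cell (0.44) ended at 0.15 at a mean FPKM of at least 5. Inflammatory cytokine and chemokine (-0.30) ended at -0.11 with the hepatocyte covariate. Antimicrobial and acute phase (-0.011) ended at -0.00956 with a pseudocount of 0.1, -0.11 with median-of-ratios scaling, -0.011 with a replicate block, -0.011 with only the 2 groups compared and -0.21 without mock replicate 2 and trained infected replicate 1. Enterocyte absorption (0.32) ended at 0.28 with no filter, 0.23 with the hepatocyte covariate, 0.33 with the egg and gonad covariate, 0.23 with the exocrine pancreas covariate and 0.21 without mock replicate 2 and trained infected replicate 1. Epithelial junction (-0.16) ended at -0.16 at a mean FPKM of at least 5, -0.12 with quantile normalization, -0.18 with the hepatocyte covariate and -0.19 without mock replicate 2 and trained infected replicate 1. Smooth muscle (0.25) ended at 0.16 at a mean FPKM of at least 5.

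Calls of these other lists ended in trained infected against mock without a change of sign. Macrophage (0.19) ended at 0.23 with the egg and gonad covariate and 0.22 without mock replicate 2 and trained infected replicate 1. Antimicrobial and acute phase (0.67) ended at 0.39 with no filter, 0.72 with scaling without pancreas and hepatocyte genes, 0.073 with the hepatocyte covariate and 0.92 with the egg and gonad covariate. The hepatocyte score shares members with that list. Cholesterol and fatty acid synthesis (-0.33) ended at -0.34 at a mean FPKM of at least 5 and -0.091 with the exocrine pancreas covariate. ER and heat stress, immediate early (-0.27) ended at -0.23 at a mean FPKM of at least 5, -0.17 with quantile normalization and -0.15 with the exocrine pancreas covariate.

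Of the largest named changes, with 1 library left out, 2 to 9 of 10 passed in infected against mock, 0 to 19 of 19 in trained infected against infected and 0 to 19 of 19 in trained infected against mock (limma). None of these changed sign in the settings run. The cause of these differences was not tested.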

Other observations

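Several metabolic and epithelial lists passed camera in 1 or 2 of the 3 comparisons, none of them with an estimated correlation. Glycolysis genes rose after infection by a median of 0.22 ± 0.11 and fell from infected to trained infected intestine by 0.29 ± 0.14 (camera adjusted p = 0.00214 and 0.00203, and 0.623 and 0.623 with an estimated correlation). ALDOC (ENSDARG00000019702), an aldolase, had 30.7 ± 2.52, 63.8 ± 13.8 and 34.9 ± 3.74 FPKM (SD, n = 3) in mock, infected and trained infected intestine, and HK1 (ENSDARG00000039452), a hexokinase, 6.2 ± 1.93, 12.0 ± 1.54 and 6.5 ± 0.495. Sterol and fatty acid synthesis genes fell after infection by 0.42 ± 0.09 (camera adjusted p = 0.0130, and 0.760 with an estimated correlation) and in trained infected intestine lay -0.33 ± 0.08 from mock (camera adjusted p = 0.00461, and 0.720 with an estimated correlation). The former median was -0.057 without mock replicate 1 (call ended), -0.68 without mock replicate 3, -0.38 without infected replicate 1 (call ended) and -0.33 without infected replicate 3 (call ended), and the latter was -0.10 without mock replicate 1 (call ended) and -0.54 without mock replicate 3. The glycolysis median after infection was 0.074 without mock replicate 1, 0.11 without mock replicate 3 and 0.13 without infected replicate 1, and from infected to trained infected intestine it was -0.055 without trained infected replicate 3. CYP1A1 (ENSDARG00000098315), which oxidizes aromatic compounds, had 23.0 ± 6.31, 9.67 ± 2.77 and 9.25 ± 1.56 FPKM (limma adjusted p = 0.124 for infected and 0.0550 for trained infected against mock).

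Lysosome rich enterocytes, cells of the gut wall that take up protein, have a list that passed after infection with a median of 0.073 ± 0.088 (camera adjusted p = 0.0120, and 0.761 with an estimated correlation). Its members were split, 18 higher and 17 lower, with 2 higher over all genes tested and 3 adjusted over the list alone. The 2 were PLAC8 and DAB2 (ENSDARG00000053091), an adaptor of endocytosis (2.73 ± 0.513, 9.72 ± 1.67 and 5.07 ± 0.368 FPKM in mock, infected and trained infected intestine). This list's median was 0.000194 without mock replicate 1 (call ended), -0.035 without mock replicate 2 (call ended), 0.16 without mock replicate 3, 0.021 without infected replicate 1 and -0.10 without infected replicate 3 (call ended). Epithelial junction genes fell from infected to trained infected intestine by 0.16 ± 0.063 (camera adjusted p = 0.0279, and 0.663 with an estimated correlation), with cldnb (ENSDARG00000009544), a claudin, at 89.8 ± 62.7 and 10.9 ± 1.69 FPKM and at 11.5 ± 5.03 in mock. Enterocyte absorption genes rose in the same comparison by 0.32 ± 0.076 (camera adjusted p = 0.0413, and 0.8 with an estimated correlation), with creb3l3a (ENSDARG00000056226), a regulator of lipid export, at 8.33 ± 1.45 and 18.9 ± 1.62 FPKM. The junction median was -0.079 without infected replicate 1, -0.14 without infected replicate 2 (call ended), -0.19 without trained infected replicate 1 (call ended) and -0.052 without trained infected replicate 3, and the absorption median was 0.36 without infected replicate 1 (call ended), 0.17 without infected replicate 2 (call ended), 0.21 without trained infected replicate 1 (call ended) and 0.31 without trained infected replicate 3 (call ended).

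B cell genes rose after infection by 0.30 ± 0.09 and stress genes by 0.18 ± 0.047, and cytotoxic cell genes fell by 0.41 ± 0.078 (camera adjusted p = 0.00113, 0.00135 and 0.0354, and 0.506, 0.663 and 0.663 with an estimated correlation). Their medians were 0.19 without infected replicate 1, 0.11 without mock replicate 3, and -0.18 without mock replicate 1 (call ended), -0.40 without mock replicate 3 (call ended) and -0.30 without infected replicate 2 (call ended). Stress genes lay -0.27 ± 0.10 from mock in trained infected intestine, and the antimicrobial list 0.67 ± 0.17 (camera adjusted p = 0.0388 and 0.0374, and 0.663 and 0.663 with an estimated correlation). The stress median was -0.21 without mock replicate 1 (call ended), -0.29 without mock replicate 3 (call ended) and -0.15 without trained infected replicate 3 (call ended), and the antimicrobial median was 0.61 without mock replicate 1 (call ended), 1.15 without mock replicate 2, 0.52 without mock replicate 3 (call ended) and 0.29 without trained infected replicate 1 (call ended). With a hepatocyte score as a covariate the antimicrobial median was 0.073 and the call ended. That score and this list share members, fgb and tfa among them, so part of the fall is built in. The antimicrobial list passed from infected to trained infected intestine with a median of -0.011 ± 0.24 and 15 of 30 members lower, and the cell cycle list with -0.33 ± 0.034 (camera adjusted p = 0.0388 and 0.00113, and 0.663 and 0.783 with an estimated correlation). The antimicrobial median was -0.011 without mock replicate 1 (call ended), -0.011 without mock replicate 2 (call ended), -0.011 without mock replicate 3 (call ended), 0.018 without infected replicate 1, 0.000768 without infected replicate 2 (call ended), -0.12 without infected replicate 3, -0.21 without trained infected replicate 1, -0.029 without trained infected replicate 2 (call ended) and 0.069 without trained infected replicate 3 (call ended), and the cell cycle median was -0.18 without infected replicate 1, -0.53 without infected replicate 2, -0.68 without trained infected replicate 1 and 0.045 without trained infected replicate 3 (call ended). Skeletal muscle, enteric nervous system, erythrocyte, endocrine pancreas, goblet and enteroendocrine, and retinoid, xenobiotic and redox lists passed in no comparison, with medians from infected to trained infected intestine of -0.15, 0.14, -0.069, -0.26, 0.074 and -0.036.

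The tests of hepatocyte RNA, ovary RNA and single libraries below were chosen after the result was seen. The tests of gene length, of scaling and of other splits of the libraries were written down before they were run. The complement list was 0.50 higher in trained infected than in infected intestine, and RNA of hepatocytes, which make most complement proteins, is a candidate source. With a hepatocyte score as a covariate its median was 0.072 ± 0.071, under the 0.25 that would remain at 50% of the change. The abundant liver gene fabp10a (ENSDARG00000038439) was at 497 FPKM in trained infected replicate 1. Elsewhere it was at 50.9 (infected replicate 1) to 210 FPKM (trained infected replicate 2). The score leaves out the 1 gene both lists share, and 58 of the 66 hepatocyte genes passed the filter in these samples. Of the 66, 14 are also on another list, and 3 are on the enterocyte list. Without trained infected replicate 1 the median was 0.27 ± 0.089, which does not separate a rise in that library alone from one in all 3. A rise of complement in liver cells after β-glucan stays open, since the design holds no sample without adjoining organs, and a rise within the gut wall is not excluded.

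The oxidative phosphorylation list was lower in trained infected than in infected intestine, at a median of -0.44, and its genes are short, 997 nt at the median. After a trend of change with gene length, fitted on the other genes, was taken off, the median was -0.49 ± 0.027, which argues against length as the source. In 1000 draws of other genes of matched length the median lay between -0.17 and 0.29. With median-of-ratios scaling the list's median was -0.55 ± 0.023. That scaling applies 1 factor per library, and it moved the median of all genes only from 0.046 to -0.040. It could therefore not have brought the list near 0, so this test does not decide whether scaling plays a part. The list fell relative to other genes with either scaling. The list holds nuclear genes for mitochondrial proteins and none of the mitochondrial genome. A change in transcripts of these nuclear genes with training may remain as a hypothesis, untested here beyond these values, as does a different mix of cells in the samples.

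The cell cycle list had a median log2 change of -0.76 from mock to infected intestine, and RNA of ovary in mock samples is a candidate source, since eggs store many cell cycle transcripts. With an egg and gonad score as a covariate the median was -0.13 ± 0.032, nearer 0 than the -0.38 that would remain at 50%. ZAR1 (ENSDARG00000019706), an egg gene, stood at 517 FPKM in mock replicate 2. Elsewhere it stood at 0.255 (trained infected replicate 3) to 193 FPKM (mock replicate 3). The 2 lists share no gene, their scores went together over the 9 libraries (r = 0.96, rho = 0.95, exact permutation p = 0.00011 and 0.00035, adjusted 0.00066 and 0.0011, and r = 0.95 without the 2 farthest libraries and within groups), and 27 of the 35 egg and gonad genes passed the filter in these samples. Without mock replicate 2 the median was -0.36 ± 0.056, which does not separate that library alone from the rest. With that covariate the list still passed camera at the preset correlation (adjusted p = 0.00719), so ovary RNA may account for most of the change, and a smaller fall in dividing gut cells stays open.

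Each comparison's 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits with as many genes is never under 0.1. In each comparison 1 of the 10 splits, the real one, gave as many genes: 46, 22 and 131 for infected against mock, trained infected against infected, and trained infected against mock, and 0 was the highest of the other splits each time (limma, with the remaining group kept in the fit).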
